A study of Mus musculus with 2 samples.

How the data were processed

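MicroRNA sequencing libraries were prepared from the hearts of 2 male mice of the B6CASTF1/J strain at 4 days after birth. This strain is the first-generation cross of the C57BL/6J and CAST/EiJ inbred lines. The labels call the libraries biological replicates 1 and 2 and describe the animals as male 03 and male 04. Both carry the same donor identifier, and the libraries were taken to come from separate animals because of these numbers. If they did not, the spread between them is technical. Both libraries were made from total RNA with a size range under 30, per the labels. They form a single group, so no comparison between conditions was made, and each animal is represented by a single library.

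The deposited tables hold raw read counts per miRNA gene and are not normalized. Their reads were aligned to the mouse mm10 assembly with GENCODE M21 genes, per the description files deposited with the tables. The aligner and its version are not given in the sources used here. Reads of CAST alleles that differ from this assembly can be lost in alignment, which was not tested. Each deposited table gives counts without regard to strand, counts on the gene's strand and counts on the opposite strand. The assignment of the columns to strands was read from the values: hairpins that overlap on opposite strands, such as Mir378a and Mir126a, have few or 0 counts in the first column and large counts in the second. Mir378a has 0 and 0 counts there in replicates 1 and 2, and Mir126a has 28 and 1. The counts on the gene's strand, called sense counts below, were used for every main result. Each table also has lines for unmapped, multi-mapped, unassigned and ambiguous reads, which name no gene and were kept out of the library sizes and tests.

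Sense counts came to 4196577 in replicate 1 and 3801738 in replicate 2. These were 43.8% and 40.9% of the 9591115 and 9293203 reads that the tables account for. Multi-mapped reads made up 38.1% and 42.3%, unmapped reads 14.1% and 13.1%, and reads outside the annotated miRNA genes 4.01% and 3.70%. Reads that were ambiguous when strand was ignored made up 11.4% and 8.25%. A single read was worth 0.238 CPM (counts scaled to the library total) in replicate 1 and 0.263 CPM in replicate 2. A gene with 0 counts may therefore still hold up to 0.715 CPM or 0.789 CPM, the level of 3 counts per library. Intervals of shares are 95% Wilson intervals, and these, the intervals of folds between genes and this limit cover counting error only, since reads of a PCR-amplified library are not independent molecules.

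All 2202 gene IDs in the tables matched miRNA genes of GENCODE M21, from which symbols, positions and host genes on the same strand were taken. A gene's count combines both arms of its hairpin and any read inside the annotated precursor. CPM were computed from the sense counts over each library's total, and log2 values are log2(CPM + 1). Ratios are given as replicate 2 over replicate 1. Of the genes, 441 had 10 or more counts over both libraries and were tested.

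Each gene's counts were compared between the libraries with a two-sided Fisher's exact test against the rest of the library, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares 2 libraries and not conditions, and it takes counting error as the only error. Spread beyond counting error was estimated as the biological coefficient of variation, the square root of edgeR's common dispersion in a fit with no group difference. It used TMM scaling (trimmed mean of M-values) and the 344 genes with 10 or more counts in each library. edgeR's quasi-likelihood test has no residual degrees of freedom in this design. edgeR's exact test with the estimated spread was run as an alternative. Its spread comes from the same 2 libraries that it compares, so few or no calls are built into it. The 18 lists of miRNA genes were fixed before the data were examined. For each, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a p-value. Neighbouring genes on the same strand within 10 kb were compared by a one-sided permutation test with 10000 resamples. Genes with and without a window of their own were compared by a two-sided permutation test with 100000 resamples.

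Hairpins were searched for 20-base windows shared with other annotated miRNA hairpins. The planned version of this search called for windows unique in the genome. The genome sequence was not used here, so copies outside annotated miRNA genes were not seen. By this search 1087 of the 2202 hairpins share at least 1 window with another hairpin and 301 have no window of their own.

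Genes named individually follow a rule set before the data were examined. It takes the 20 genes of highest mean CPM and the 4 most abundant members of each list. It also takes the 5 highest and the 5 lowest ratios among genes past the Fisher threshold with a mean count of at least 100. Mir208a, Mir208b, Mir499, Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2, Mir122 and Mir451a are named whatever their values. Other genes that appear were chosen after their values were seen, and this is said beside them.

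The statistics were tested on simulated data drawn from the real means and library sizes. For the comparison of the libraries, 438 simulated genes were tested, with 2-fold changes in some of them and counting error as the only spread. Fisher's exact test recovered 99.2% of 125 changed genes at 100 or more counts and 16.2% of 68 at 10 to 99 counts. It called 1.99% and 0% of unchanged genes at those levels. With a simulated coefficient of variation of 0.4 and no other change, edgeR estimated 0.377 over 351 genes. In that simulation Fisher's exact test called 270 of 438 genes and edgeR's exact test called 0.

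Alternatives tried were the counts without regard to strand, TMM and DESeq2 scaling and other count minimums. A pseudocount of 10 CPM, other denominators, other distances and window lengths, and leaving out each library were also tried. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.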

Results

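MicroRNAs were profiled in the hearts of 2 male B6CASTF1/J mice at postnatal day 4, with 1 library per animal. Sense counts over annotated miRNA genes numbered 4196577 in replicate 1 and 3801738 in replicate 2. Errors given as ± are SDs over these 2 libraries (n = 2). The labels state no question beyond the profile itself. The questions addressed are therefore which miRNAs made up the neonatal heart libraries, how the known marker groups were represented, and how far the libraries of the 2 animals differed.

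A small set of miRNAs held most of the sense counts. The 3657699 and 3929811 multi-mapped reads of replicates 1 and 2 are not in these counts. The order below is therefore that of reads assigned to a single gene, and miRNAs with near-identical copies can rank too low. Mir378a, which lies in an intron of Ppargc1b, a transcriptional coactivator gene of mitochondrial metabolism, was the most abundant gene with 11.8% ± 0.12 of sense counts. Its hairpin (chromosome 18, 61397835 to 61397900, minus strand, mm10) was followed by Mirlet7i at 9.04% ± 0.30 (chromosome 10, 122985640 to 122985724, intergenic). Mir126a, an endothelial miRNA annotated in an intron of Gm20532 (chromosome 2, 26591357 to 26591429), averaged 7.93% ± 4.23. Mirlet7g in an intron of Wdr82 (chromosome 9, 106178840 to 106178927) held 7.57% ± 0.65. Mir143, a smooth muscle miRNA (chromosome 18, 61649196 to 61649258, intergenic), held 6.03% ± 1.87.

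The next genes were Mir23b at 4.53% ± 0.73, Mir23a at 3.65% ± 0.51 and Mir335, in an intron of the imprinted gene Mest, at 3.33% ± 1.14. Mir26b in an intron of Ctdsp1 held 2.71% ± 0.66, and Mir322 on chromosome X held 2.62% ± 0.45. The 10 most abundant genes together took 57.6% of the counts in replicate 1 (95% Wilson interval 57.57 to 57.67) and 60.7% in replicate 2 (60.68 to 60.77), and the 20 most abundant took 76.0% ± 2.53. The remaining members of the top 20 lay between 1.26% and 2.33%. They were Mir30d, Mir99a, Mirlet7b, Mir99b, Mirlet7d, Mir652, Mir139, Mir30a, Mir21a and Mir30e. Order within this set was not fixed by the data where SDs overlap: Mir126a held 10.9% of replicate 1 (95% Wilson interval 10.89 to 10.95) and 4.93% of replicate 2 (4.91 to 4.95), so it stood above Mirlet7i in replicate 1 and below Mirlet7g in replicate 2.

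**Figure D1:**
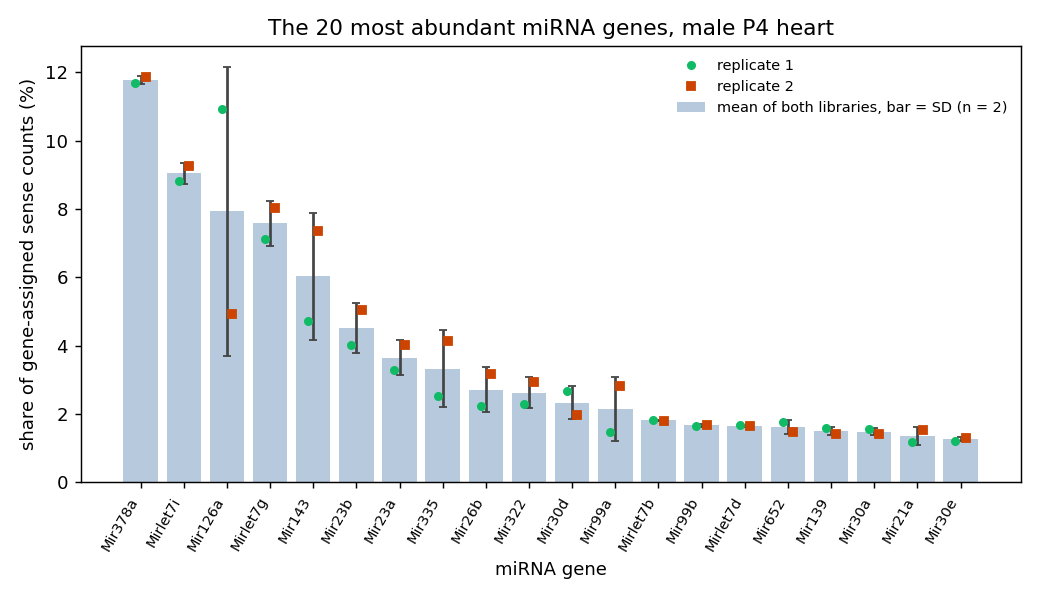
Share of sense counts (%, vertical axis) for the 20 most abundant miRNA genes in male postnatal day 4 heart. Bars are means of the 2 libraries, lines their SD, circles replicate 1 and squares replicate 2. Mir378a is nearly equal in both at 11.7% and 11.9%, while Mir126a is at 10.9% in replicate 1 and 4.93% in replicate 2.

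Detection was limited to a minority of annotated genes. Of the 2202 miRNA genes, 1458 had 0 counts in both libraries and 344 had 10 or more counts in each. A level of 1 CPM or more was reached in both libraries by 419 genes. Genes inside introns of annotated host genes contributed 56.4% of the counts and intergenic genes 29.4%, averaged over both libraries. Genes overlapping exons with no coding sequence or untranslated region contributed 12.0%, those in untranslated regions 2.13% and those in coding exons 0.077%.

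Of the striated muscle miRNAs, those encoded in introns of the myosin heavy chain genes had the most reads among those assigned to a single gene. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), reached 5214 ± 821 CPM. Mir208b, in an intron of the slow myosin gene Myh7 (chromosome 14, 54975700 to 54975776), reached 4067 ± 1558 CPM. Mir208a, in an intron of the adult ventricular myosin gene Myh6 (chromosome 14, 54949060 to 54949142), reached 1675 ± 588 CPM. Within each library, Mir208b exceeded Mir208a by 2.47-fold (95% interval 2.41 to 2.53) and 2.35-fold (2.28 to 2.44). The log2 ratio of Mir208a to Mir208b was -1.27 ± 0.05, so its distance from 0 was far larger than the spread between the libraries. These are ratios of reads of different miRNAs. An error that recurs in both libraries would not show in that spread and was not tested. Mir499 exceeded Mir208a by 2.77-fold (2.70 to 2.84) and 3.68-fold (3.56 to 3.80), a log2 ratio of 1.67 ± 0.29.

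The other muscle miRNAs had few reads assigned. Mir1a-2 on chromosome 18 had 139 and 207 counts in replicates 1 and 2, and its neighbour Mir133a-1 had 11 and 29. The copies on chromosome 2 had 10 and 13 counts for Mir1a-1, and 7 and 5 for Mir133a-2. All 4 of these hairpins share 20-base windows with near-identical genes, and reads that match several places are not in the gene counts. These values are therefore uncertain as levels of miR-1 and miR-133. The striated muscle list as a whole, with 9 of 10 members tested, held 1.31% of counts in replicate 1 (95% Wilson interval 1.30 to 1.32) and 0.896% in replicate 2 (0.887 to 0.906).

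The let-7 and miR-98 list, a family tied to differentiated cells, was the largest and took 22.1% ± 0.90 of counts. All of its 12 members had 10 or more counts in each library, led by Mirlet7i, Mirlet7g, Mirlet7b and Mirlet7d. The paired miR-23/27/24 clusters took 8.75% ± 1.08, nearly all of it from Mir23b and Mir23a; Mir27b and Mir27a held 0.482% ± 0.138 and 0.077% ± 0.014. The miR-30 family took 5.17% ± 0.55, with Mir30d, Mir30a and Mir30e far above Mir30c-2 at 0.040% ± 0.006. The miR-15/16 family took 3.36% ± 0.12, of which Mir322 was the main part, followed by Mir15b at 0.282% ± 0.240, Mir195a at 0.178% ± 0.190 and Mir15a at 0.160% ± 0.106. The miR-17-92 cluster and its paralogs, which favour proliferation, took 2.01% ± 0.13, led by Mir17 at 0.714% ± 0.150, Mir93 at 0.671% ± 0.102, Mir20a at 0.260% ± 0.052 and Mir92-1 at 0.162% ± 0.054. Some members of each of these families share 20-base windows with other hairpins, so their gene counts are lower limits of the family's reads.

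Among miRNAs of other cell types, the endothelial list took 8.38% ± 4.01, and Mir126a provided most of it. Mir100, Mir10b and Mir10a held 0.213% ± 0.095, 0.106% ± 0.081 and 0.093% ± 0.039. The smooth muscle and pericyte list took 6.40% ± 2.18 from Mir143 and Mir145a, the latter at 0.375% ± 0.318; Mir145b had 0 and 4 counts. The fibroblast and matrix list took 1.79% ± 0.17, led by Mir21a at 1.36% ± 0.27, Mir214 at 0.381% ± 0.406, Mir29a at 0.037% ± 0.024 and Mir29c at 0.0066% ± 0.0024. Mir29a held 0.054% in replicate 1 and 0.020% in replicate 2. White blood cell miRNAs took 0.240% ± 0.001, led by Mir155, Mir146, Mir150 and Mir142. Red blood cell miRNAs took 0.045% ± 0.007, with Mir451a at 234 CPM in each library, then Mir486 at 123 ± 28.0 CPM and Mir144 at 90.2 ± 37.6 CPM, and Mir451b at 0 counts.

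Marker lists of tissues other than heart had low shares, and some of their members had no reads. Counts were 0 in both libraries for 4 of 17 neuron genes, 2 of 10 liver, gut and pancreas genes and 5 of 14 pluripotent cell genes, and for 0 of 10 epithelium genes, beside 1458 of 2202 over all genes. A 20-base window is shared with another hairpin by 14 of the 17 neuron genes, so that list's share and counts are lower limits. The same holds for 2 liver, gut and pancreas genes and 4 pluripotent cell genes, and for 0 epithelium genes. The neuron list took 0.114% ± 0.020, led by Mir132 at 560 ± 129 CPM, which is not restricted to neurons, then Mir128-1 at 291 ± 56.0 CPM, Mir138-1 at 81.8 ± 3.41 CPM and Mir138-2 at 61.6 ± 7.54 CPM. The epithelium list took 0.051% ± 0.014, with Mir200c at 243 ± 70.6 CPM, Mir203 at 138 ± 117 CPM, Mir200b at 42.6 ± 32.4 CPM and Mir429 at 26.4 ± 4.17 CPM. Mir203 and Mir200b changed places between the libraries, with 55.8 and 65.5 CPM in replicate 1 and 221 and 19.7 CPM in replicate 2. The liver, gut and pancreas list took 0.045% ± 0.038, with the liver miRNA Mir122 at 207 ± 144 CPM, Mir215 at 178 ± 199 CPM, Mir194-1 at 28.4 ± 18.2 CPM and Mir194-2 at 20.8 ± 12.7 CPM. The pluripotent cell list took 0.0048% ± 0.0004, led by Mir302d at 20.0 ± 1.05 CPM, Mir302a at 13.2 ± 2.87 CPM, Mir302b at 5.82 ± 1.54 CPM and Mir294 at 2.44 ± 1.76 CPM.

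Imprinted miRNA loci were well represented. In the Dlk1-Dio3 cluster on chromosome 12, 45 of 52 genes had 10 or more counts in each library and together took 2.57% ± 0.12. Mir127 held 0.535% ± 0.071, Mir379 0.415% ± 0.070, Mir411 0.344% ± 0.082 and Mir541 0.253% ± 0.00081. The other imprinted loci took 3.87% ± 0.88, most of it from Mir335, with Mir298 at 0.290% ± 0.173, Mir296 at 0.132% ± 0.056 and Mir483 at 0.115% ± 0.030. Mir298 held 0.413% in replicate 1 and 0.168% in replicate 2. The hypoxia and stress list took 1.42% ± 1.22, most of it from Mir22 at 1.19% ± 1.11, followed by Mir34a at 0.097% ± 0.050, Mir210 at 0.063% ± 0.056 and Mir132 at 0.056% ± 0.013. Mir34a held 0.133% in replicate 1 and 0.062% in replicate 2.

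**Figure D2:**
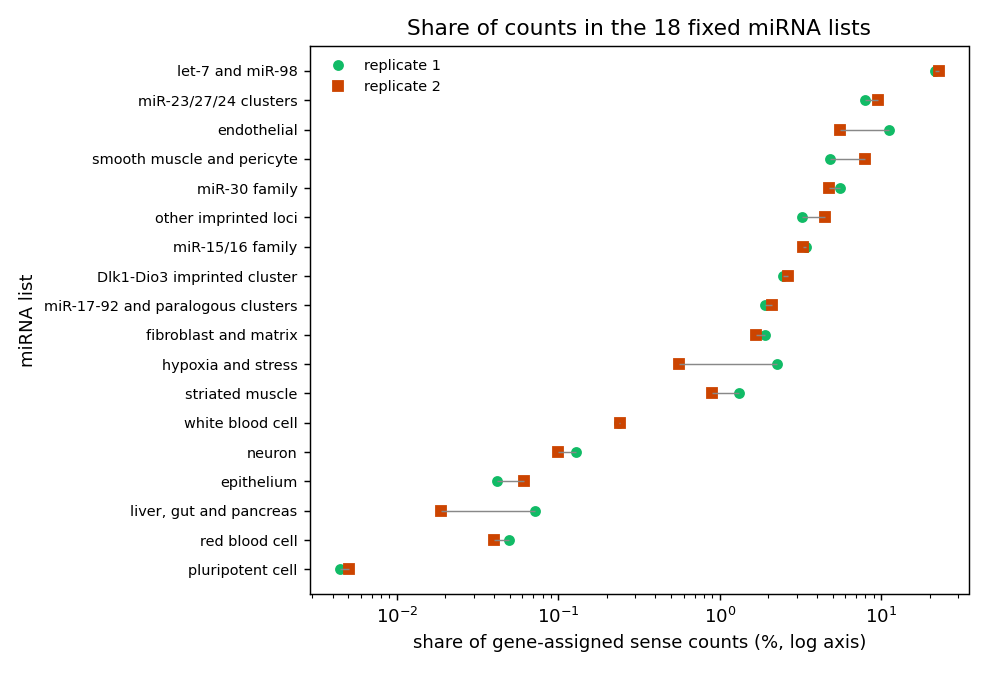
Share of sense counts (%, horizontal log axis) in each of the 18 miRNA lists (vertical axis). Circles are replicate 1 and squares replicate 2, joined by a line. The let-7 and miR-98 list is highest at 21.4% and 22.7%, and the widest gaps are in the hypoxia and stress list (2.28% and 0.559%) and the liver, gut and pancreas list (0.072% and 0.019%).

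The libraries of the 2 animals ranked miRNAs alike but differed in many single genes by far more than counting error. Across the 441 tested genes, Pearson's r of log2(CPM + 1) was 0.979 (bootstrap 95% interval 0.973 to 0.983) and Spearman's rho was 0.966 (0.954 to 0.974). These are correlations across genes, which are not independent replicates. The biological coefficient of variation was 0.381 (bootstrap 95% interval 0.339 to 0.419). This bootstrap redrew genes within the same 2 libraries. Its interval leaves out the uncertainty from having only 2 animals.

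The widest gaps toward replicate 1 were in Mir215, which had 319 CPM there and 37.1 CPM in replicate 2, and in Mir195a, with 3125 and 437 CPM. Mir214, in an exon of Dnm3os (chromosome 1, 162223368 to 162223477), had 6683 and 941 CPM. Mir301, in an intron of Ska2, had 2415 and 366 CPM, and Mir665, in the Dlk1-Dio3 cluster, had 181 and 29.7 CPM. Their log2 ratios ran from -3.07 for Mir215 to -2.57 for Mir665.

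The widest gaps toward replicate 2 were in Mir26a-1, in an intron of Ctdspl (chromosome 9, 119031796 to 119031885), with 7.63 and 83.6 CPM, and in Mir140, within Wwp2 (chromosome 8, 107551244 to 107551313), with 1214 and 6173 CPM. Mir669e had 46 and 215 counts, Mir145a 1501 and 5998 CPM, and Mir203 55.8 and 221 CPM. Their log2 ratios ran from 3.29 for Mir26a-1 to 1.97 for Mir203. The hairpins of Mir26a-1 and Mir669e share windows with other genes, so their counts are uncertain.

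In Fisher's exact test with Benjamini-Hochberg adjustment, 251 of 441 genes differed between the libraries at an adjusted p under 0.05, with 90 higher and 161 lower in replicate 2. The median log2 ratio of tested genes was -0.26, and TMM scaling shifted all ratios by 0.30 and DESeq2 scaling by 0.27. The split was 135 higher and 106 lower with TMM scaling, and 130 and 111 with DESeq2 scaling, so the direction of the excess depended on the scaling. edgeR's exact test, which takes its spread from the same 2 libraries it compares, called 0 of 441 genes at an adjusted p under 0.05. That outcome is largely fixed by the design and does not show that the genes were equal. Its unadjusted p was under 0.05 for 1 gene, Mir26a-1 (p = 0.048, edgeR's exact test). Of the 243 genes with a mean count of at least 100, 41 (16.9%) differed by more than 2-fold. Of these, 9 were higher and 32 lower in replicate 2. After TMM scaling 41 genes, in part others, were over 2-fold apart, with 20 higher and 21 lower. In the same direction under both scalings were 30 genes.

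**Figure D3:**
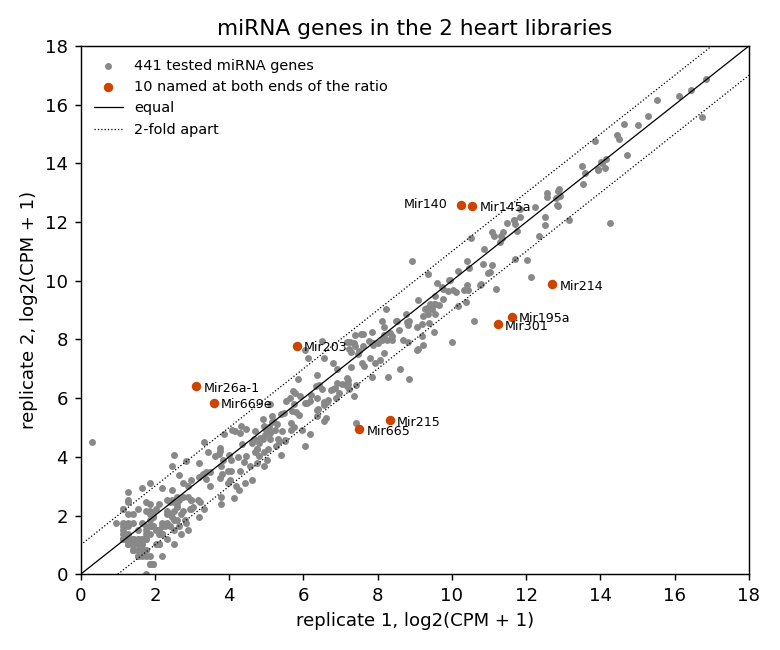
Level of each of the 441 tested miRNA genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both as log2(CPM + 1). The solid line marks equal levels and the dotted lines a 2-fold difference. Orange points are the 10 genes named at both ends of the ratio, from Mir26a-1 at a log2 ratio of 3.29 to Mir215 at -3.07.

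Of the 18 lists, 5 had a median log2 ratio outside the 95% range of matched random lists. The range moves with the scaling, so a list's place in it does not depend on the overall shift. Random lists were not matched on shared sequence or position, whereas several lists hold related genes. Hairpin pairs with sequence in common had closer ratios than permuted pairs, with a mean difference of 0.61 against 0.89. Neighbouring genes were not shown to, with 0.91 against 0.90. The random range may thus be too narrow for lists of related genes, which was not tested. The endothelial list had a median of 0.70 (random range -0.88 to 0.25), above all of its random lists (percentile 100), and 4 of its 6 tested members were higher and 1 lower in replicate 2 by Fisher's exact test. Its share of counts went the other way, at 11.2% (95% Wilson interval 11.18 to 11.24) in replicate 1 and 5.54% (5.52 to 5.56) in replicate 2, because Mir126a, its most abundant member, had a log2 ratio of -1.15. Mir10b, Mir100 and Mir10a had log2 ratios of 1.74, 0.94 and 0.88. The smooth muscle and pericyte list had a median of 1.32 (-1.31 to 1.13) from only 2 tested members, Mir145a at 2.00 and Mir143 at 0.64. The white blood cell list had a median of 0.41 (-0.79 to 0.39), with 5 of 7 members higher and 2 lower. Its examples Mir142 and Mir150 had log2 ratios of 0.63 and 0.41, and Mir155 and Mir146 had -0.24 and -0.31.

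At the low end, the liver, gut and pancreas list had a median of -1.35 (-0.85 to 0.46), with 5 of 7 members lower and 1 higher in replicate 2. Mir122, Mir194-1 and Mir194-2 had log2 ratios of -1.54, -1.35 and -1.26. The miR-15/16 family had a median of -1.24 (-0.90 to 0.31), with 5 of 7 members lower and 1 higher. Mir195a, Mir15b and Mir15a had log2 ratios of -2.84, -2.01 and -1.47, whereas Mir322 had 0.36. With counts taken without regard to strand, this family's median of -0.96 stayed inside the range of random lists. With no count minimum the family's median was -0.74 over 8 members, still outside that range (percentile 2.13). With a pseudocount of 10 CPM the liver, gut and pancreas median was -0.87 (percentile 0.01). The white blood cell median was 0.71 with TMM scaling and 0.68 with DESeq2 scaling, which add the overall shift.

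The other 13 lists lay within the random range. Their medians were -0.67 for fibroblast and matrix, -0.55 for other imprinted loci, -0.47 for hypoxia and stress, -0.47 for red blood cell, -0.41 for the Dlk1-Dio3 cluster, -0.37 for neuron and -0.31 for epithelium. They were -0.20 for striated muscle, -0.14 for the miR-30 family, -0.05 for the miR-23/27/24 clusters and -0.03 for miR-17-92 and its paralogs, which all turn positive with TMM scaling, at 0.10, 0.16, 0.26 and 0.27. They were 0.09 for let-7 and miR-98 and 0.10 for pluripotent cell. With counts taken without regard to strand, the let-7 and miR-98 median turned to -0.02 over 10 genes. Mir22 and Mir210 of the hypoxia and stress list had log2 ratios of -2.29 and -2.10, while 2 of the 7 members had positive values.

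Fisher's exact test adjusted over all tested genes called members in both directions in most of these 13 lists, as scaled by total counts. In let-7 and miR-98, 6 of 12 tested genes were higher and 4 lower in replicate 2, and in miR-17-92 and its paralogs 4 of 13 were higher and 5 lower. In striated muscle 2 of 9 were higher and 3 lower, in the miR-23/27/24 clusters 3 of 6 and 3, and in the miR-30 family 1 of 6 and 4. In fibroblast and matrix 1 of 8 was higher and 4 lower, in the Dlk1-Dio3 cluster 10 of 45 and 26, and in other imprinted loci 2 of 5 and 3. In neuron 2 of 12 were higher and 6 lower, in epithelium 3 of 9 and 4, in hypoxia and stress 2 of 7 and 4, and in red blood cell 0 of 3 and 2. No pluripotent cell gene of the 7 tested was called.

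Adjusted over the list alone, the test called 11 of 12 let-7 and miR-98 genes, 11 of 13 miR-17-92 genes, 36 of 45 Dlk1-Dio3 genes, 8 of 12 neuron genes and 7 of 9 genes each in striated muscle and epithelium. It called 6 of 8 fibroblast and matrix genes, 6 of 7 each in the miR-15/16 family, the liver, gut and pancreas list and the hypoxia and stress list, and 7 of 7 white blood cell genes. Adjusted over the list alone, it also called 6 of 6 genes of the miR-23/27/24 clusters, 5 of 6 each in the endothelial list and the miR-30 family, 5 of 5 of the other imprinted loci, 2 of 3 red blood cell genes, 2 of 2 smooth muscle and pericyte genes and 0 of 7 pluripotent cell genes.

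Neighbouring miRNA genes were closer in level than genes paired at random, although still far apart. Over 121 pairs of adjacent tested genes on the same strand within 10 kb, the mean absolute difference of log2(CPM + 1) was 2.94, against 4.36 when levels were permuted among genes (one-sided permutation p = 1e-04, the smallest these permutations can give). Levels were permuted among all tested genes, with or without neighbours. A general difference in level between clustered and other genes was therefore not separated from likeness of neighbours. Clusters of 33 and 11 genes on chromosome 12 gave many linked pairs, and this comparison was not repeated without them. The 3-gene cluster of Mir99b, Mirlet7e and Mir125a stayed within 2.47-fold from highest to lowest. The 7-gene cluster of Mir322 and its neighbours on chromosome X spanned 1917-fold, with Mir322 at its top. This cluster includes Mir450-1 and Mir450-2, which share windows with other hairpins, so their counts are lower limits. Their mean log2(CPM + 1) was 4.43, against 8.55 for Mir450b, which shares none. The span of the cluster may therefore be overstated. Mir451a and Mir144 differed by 2.59-fold. The clusters given here as examples were chosen after their values were seen.

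Genes with no 20-base window of their own could hardly be compared with the rest, because only 3 of them were among the 441 tested. Their median log2(CPM + 1) differed from that of the others by -3.29 (two-sided permutation p = 0.25). The difference was -0.22 (permutation p = 0.93) with no count minimum, where 4 such genes entered among 744, and -1.80 (permutation p = 0.37) with a pseudocount of 10 CPM.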

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

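The rule for these entries is reads on the strand opposite to the gene, which no comparison in the report used, above the limit that a count of 0 allows. With no control samples, that limit was 3 counts in each library. It was passed in both libraries by 5 genes that overlap no other annotated miRNA gene. Mir122 had 26 opposite-strand reads over both libraries (8 and 18), beside 1296 and 400 sense counts. Mir203 and Mir324 each had 19, with 9 and 10 in replicates 1 and 2. Mir708 had 18 (6 and 12) beside 703 and 1077 sense counts. Mir5620 had 13 (9 and 4) beside only 1 and 5 sense counts, so it is the gene of these 5 with more reads against its strand than along it. No explanation of these reads was tested.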

How the results depend on the processing

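Of 59 comparisons of a main result with an alternative, 50 kept their direction, side of the threshold or value within the spread. Some of these outcomes were fixed in advance. With 2 libraries, a share or myosin-intron ratio from either library alone always lies within the SD of both, so those comparisons show nothing on stability. The level difference by shared windows was reversed, from -3.29 to 0.23 (p = 0.71, permutation test), when genes sharing any window were taken, an alternative chosen after seeing the data; neither value passed the threshold and the cause was not tested. With a count minimum of 100 it gave no value, since 0 such genes were left. The library differences fell from 251 to 0 genes with edgeR's exact test, whose spread is estimated from the very libraries compared, so that this fall is built into the test and shows nothing on stability; with the other alternatives they ran from 223 to 241. Pearson's r was 0.984 and rho 0.910 with no count minimum, which adds genes near 0, and r was 0.965 with a minimum of 100. The share of the 10 most abundant genes was 51.2% without regard to strand, where overlapping hairpins are lost, and 25.03% of all reads. Detected genes numbered 601 and 227 with minimums of 1 and 100 counts. Leaving out each library gave shares of 57.6% to 60.7%, detected genes of 354 to 388, and a log2 ratio of Mir208a to Mir208b of -1.31 to -1.23. Of 124 list medians under alternatives, 123 kept their side of the random range, and the exception was the miR-15/16 family without regard to strand (-0.96). TMM and DESeq2 scaling shift all ratios alike and cannot move a list within that range. The list medians under these 2 scalings, and the number of lists outside the range, were therefore bound to stay. No paired analysis was possible because there is a single group. Depth limits genes under 100 counts, where simulated 2-fold changes were recovered in only 16.2% of cases with counting error alone. Spread between the libraries is a further limit, which that simulation left out. With a simulated coefficient of variation of 0.4 and no other change, Fisher's exact test called 270 of 438 genes.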

Other observations

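Chromosomes contributed unevenly. Chromosome 18, which carries Mir378a, Mir143 and Mir145a, held 18.2% ± 2.29 of sense counts, and chromosome 2 held 10.5% ± 4.42. Chromosome 12 had the most genes with 10 or more counts in each library, 56, but held only 2.89% ± 0.21 of the counts. Chromosome X held 7.09% ± 0.36 from 33 such genes, led by Mir322.

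The median ratio of some clusters of neighbouring genes lay far from the overall median of -0.26. The Sfmbt2 intron cluster of Mir669 and Mir467 genes on chromosome 2 (10467495 to 10474027) had a median log2 ratio of 0.78, and its larger part (10505721 to 10518279) had 0.33. Mir194-1 and Mir215, adjacent on chromosome 1, had a median of -2.21. Mir497 and Mir195a, adjacent on chromosome 11, had -2.04, and Mir25, Mir93 and Mir106b on chromosome 5 had -1.42, although Mir93 itself had 0.31. Mir145a and Mir143, adjacent on chromosome 18, had 1.32. These clusters were chosen after their values were seen.

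All of the tests that follow were chosen after the counts had been seen. The miR-1 and miR-133 genes had few reads for a heart library. Low content of heart muscle RNA predicted low ranks for the myosin-intron miRNAs, whose median percentile among tested genes was 91.6 (86.6 for Mir208a). Heart muscle RNA was thus present, but such a rank cannot tell how much. By mean CPM among the 2202 genes, of which 1458 had 0 counts in both libraries, Mir499, Mir208b and Mir208a had ranks 33, 37 and 59. The liver miRNA Mir122 had rank 138 on that scale. A miRNA of another tissue was thus detected too, at a lower level than these 3. Loss of reads shared between near-identical copies may account for the low counts, and the 5 tested miR-1 and miR-133 genes share a window, as do 93 of 441 tested genes, but Mir133c shares none and has 0 counts in both libraries. Within 19 families, members that share windows were lower in 12, with a median log2 difference of -0.41 (permutation p = 0.34), and a second version limited to 16 related families gave 10, -0.70 and p = 0.48 (exact permutation test). These comparisons cannot decide the question, because families differ too much in level and multi-mapped reads name no gene. The 0 counts of Mir133c, a different gene, cannot decide it either. Mir1a-1 and Mir1a-2 each share 9 windows, and Mir133a-1 and Mir133a-2 each share 17. Any read within such a shared stretch is left out of the gene counts. The low counts are therefore no measure of miR-1 and miR-133 levels, and loss of reads cannot be told apart from truly low levels.

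Many miRNAs were far apart between the 2 libraries, 41 of 243 by more than 2-fold. Library size as the whole cause is argued against: 41 genes were over 2-fold apart with TMM scaling too, and 30 of them were so in the same direction under both scalings. For transcription of the locus or cell makeup as the whole cause, neighbours of 21 far-apart genes would be displaced as much as the genes themselves, by 1.58; they were displaced by 0.37 (95% interval -0.0004 to 0.81, permutation p = 0.064, same side in 14). For a step acting alike on hairpins that share 12 bases, partners of 16 such genes were displaced by 0.13 (-0.23 to 0.51, p = 0.57, permutation test) against 1.71, on the same side in 7. A part played by either, steps that depend on the ends of the mature RNA, and a difference between the animals remain open, because each animal has a single library.

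Before those partner tests, 5 sets of gene pairs had been compared among those of the 243 genes with a partner or neighbour, 61 to 103 genes per set, and these wider sets do not bear on the far-apart genes alone. Pairs sharing 12 bases at different loci had closer ratios than permuted pairs, with a mean difference of 0.61 against 0.89 over 92 pairs (p = 0.0018, permutation test). This was 0.63 (p = 0.010) without pairs that share 20 bases, and 0.73 (p = 0.057) without let-7 pairs (same permutation test), so part of it rests on the let-7 genes. Neighbouring genes were not shown to have closer ratios than permuted pairs, with 0.91 against 0.90 over 73 pairs (permutation p = 0.57) and 1.03 against 0.89 off chromosome 12 (permutation p = 0.83). Counting error alone would give 0.090 for the 73 pairs.

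Hairpins with no 20-base window of their own reached 10 counts over both libraries in 3 of 301 cases (1.00%), against 438 of 1901 others (23.0%). Reads that match several places are not in the gene counts, so this gap largely restates how reads were counted. Of the former, 250 carry the symbol of a predicted gene (Gm), as do 771 of the others, and detection was not compared within either class.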
